A study of Mus musculus with 12 samples.

How the data were processed

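Total RNA from 3 undifferentiated and 3 differentiated mouse mammosphere samples was prepared with TRIzol and hybridised to the Affymetrix chips MOE430A and MOE430B, per the labels. The deposited values are MAS5 signals, an intensity on a linear scale with 1 value per probe set and array, and per the labels MAS5 made them; its version is not given in the sources used here. In the deposited tables every array has the same trimmed mean (2% taken off each end), 1500.5 on MOE430A and 1500.2 on MOE430B, so each array had been scaled to a common target by the authors. Detection calls were not used here. The instrument records of the arrays gave the fluidics station and the scan session: the undifferentiated arrays were run on station 2 and the differentiated on station 1, and the arrays of undifferentiated sample 1 were scanned in session 2 and all others in session 1.

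Probe sets were given gene symbols through the probe-to-gene tables of the platforms and a RefSeq gene table (assembly GRCm38.p6), used for symbols only. Of 22690 probe sets on MOE430A, 20393 are paired with 1 gene, of which 20364 matched the RefSeq table, 691 with several genes and 1606 with none. Of 22575 on MOE430B the numbers are 14674, 14499, 245 and 7656. Probe sets with several genes or none entered the tests but are not named. The 64 AFFX control probe sets of each chip were left out of the tests.

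The analysis used R 4.3.3 and limma 3.58.1, with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 for tables and figures. Arrays of a chip were scaled to their common trimmed mean, an offset of 5% of it (75 signal units) was added, and log2 values were taken. Probe sets with a mean signal over the 6 arrays of at least 20% of the trimmed mean were tested, 15939 on MOE430A and 17915 on MOE430B. limma's lmFit and eBayes compared the differentiated with the undifferentiated samples on each chip apart, with no covariate, and p-values were adjusted by Benjamini and Hochberg over the probe sets of the chip, with a threshold of 0.05. All adjusted p-values of genes in the text come from this limma test, and each log2 fold change carries limma's SE. The prior degrees of freedom were 3.08 on MOE430A and 2.78 on MOE430B, and the median residual SD was 0.21 and 0.446 on the log2 scale.

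A gene is shown by its tested probe set with the highest mean signal on MOE430A, or on MOE430B where it was tested on that chip alone. Other probe sets of a gene did not always pass. For Acta2, Ptx3, Etv4, Spry2, Ddit3, Tgfbr3, Sdhd, Cdh3, Klf4, Eng, Stat2, Gpam, Gli2 and Nefl the other one tested pointed the same way without passing. The 32 gene lists, the named genes, the tests and most alternatives were chosen before the data were examined. The rule for named genes takes the 10 largest rises and 10 largest falls in fitted log2 fold change on MOE430A and the 3 and 3 largest on MOE430B among genes that passed with no overlap between states, up to 2 rises and 2 falls from each list, and 15 marker genes whatever their values. Lists were tested with limma's camera on MOE430A, with a preset correlation of 0.01 between genes, two-sided, and adjusted over the 32 lists; camera with an estimated correlation and fry were run beside it. Counts of list members that passed are given over all probe sets tested and adjusted over the list alone.

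The background is the highest trpn control signal of an array, 515.5 to 829.8 on MOE430A and 1674 to 2995 on MOE430B. Where all 3 values of a state lay below it, that state's values were raised to the background. The ratio of geometric means is then given as a lower bound. Of 2771 genes that passed, 602 had 1 such state and a further 139 had both states below. Where only some values of a state lay below it, as for Egr2, Mmp10, Cd34, Notch1 and Csn3, the fitted change is given and its size is uncertain. A gene counts as above background on a sample if any of its probe sets is, on either chip; this definition was set after the values had been seen, as was the use of the trpn controls. Levels of unlike probe sets were not compared with each other, only counted as above or below that background.

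Tests on simulated data, with the real means and residual spread and 200 changed probe sets, recovered 2.99% of 1.5-fold, 38.8% of 2-fold and 87.9% of 4-fold changes among 15939 probe sets of MOE430A, and 9.47% of the 95 calls were false. Among 17915 probe sets of MOE430B, 0%, 0% and 22.7% were recovered. A shift of 0.5 (log2) given to a list among 9484 genes was called in 20 of 20 runs, and 1 of 620 tests of other lists was called. The simulated genes varied independently, so these runs do not test how camera fares with genes that move together. The 200 changed probe sets are far fewer than the 4550 that passed on MOE430A, so the recovery rates need not hold there. The alternatives tried were the values as deposited, quantile normalization, other offsets and filters, a trend and robust prior, the sample number and the scan session as blocks, leaving out each sample, a fold limit, adjustment over both chips, the mean of all probe sets of a gene, and lists with genes of MOE430B added. After the control probe sets had been seen, scaling on the poly-A or hybridisation controls, a filter at the trpn controls and leaving out differentiated samples 1 and 4 were added.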

Results

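RNA from mouse mammospheres was measured on Affymetrix arrays in an undifferentiated and a differentiated state. Mammospheres are floating clusters grown from mammary gland cells, and the labels describe the undifferentiated ones, at passage 3, as believed to hold stem and progenitor cells. They grew with heparin, B-27 and 2 added growth factors, EGF and basic FGF, and the submitters estimated 90% purity with 10% myoepithelial cells. The differentiated samples spent 6 days on collagen-coated dishes in high-glucose DMEM with 5% fetal bovine serum, and the submitters estimated 50% myoepithelial and 50% luminal cells. Each state has 3 RNA samples, numbered 1, 2 and 4, and each sample was hybridised to the chips MOE430A and MOE430B, for 12 arrays in all. The labels do not say whether the 3 samples of a state came from separate cultures or animals, so every p-value measures the spread between these RNA samples, which can be technical spread. Medium, serum, attachment and fluidics station differ between the states in the same way as the state itself and cannot be told apart from it.

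The trimmed mean signal was 1500.5 on the MOE430A arrays and 1500.2 on the MOE430B arrays, and the number of arrays limits the precision. Across probe sets, pairs of undifferentiated MOE430A arrays correlated at Pearson's r from 0.968 to 0.972, pairs of differentiated ones from 0.942 to 0.955, and pairs of unlike state from 0.834 to 0.864. On MOE430B these ranges were 0.855 to 0.858, 0.776 to 0.804 and 0.726 to 0.784. These r values are across probe sets, which are not independent replicates. The trpn control probe sets, designed for bacterial tryptophan operon sequence, served as the background, and a median of 49.5% of MOE430A probe sets and 79.0% of MOE430B probe sets lay below the highest of them on an array. Control transcripts added at hybridisation read higher in the differentiated arrays of MOE430A, by 2.95-fold in sample 1, 1.53-fold in sample 2 and 2.91-fold in sample 4 over the undifferentiated mean.

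The comparison addresses how gene expression differs between mammospheres and the cells they give on collagen with serum. Contractile, matrix, hypoxia-response and insulin-like growth factor genes were higher in the differentiated samples, and genes of the cell cycle and of the response to growth factor signalling were lower. Of these list calls only that of the cell cycle held with an estimated correlation between genes (adjusted p = 0.0302 with an estimated correlation, against 0.0513 to 0.288 for the others). On its brightest MOE430A probe set Acta2, the smooth muscle actin of myoepithelial and other contractile cells, rose from a signal of 5580 ± 251.5 (SD, n = 3) to 50040 ± 5416 (SD, n = 3). The other Acta2 probe set tested pointed up without passing. Mki67, a marker of dividing cells, fell from 2910 ± 30.5 to 860.8 ± 104.8. Dusp6, a phosphatase induced by ERK signalling, fell from 8992 ± 1167 to 370.3 ± 169.9, with all differentiated values below the background, and its probe set was at least 12.3-fold lower.

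Of 15939 probe sets tested on MOE430A with limma, 4550 passed an adjusted p of 0.05, 2252 of them higher and 2298 lower in the differentiated samples. A change of at least 2-fold was seen in 754 of the higher and 900 of the lower ones. Taking 1 probe set per gene, 1345 genes rose and 1316 fell out of 9484. The 3 values of a state lay wholly above those of the other state for 47.7% of the tested probe sets, where chance gives 10%, and for 99.9% of those that passed. On MOE430B 328 of 17915 probe sets passed, 128 higher and 200 lower, and among 5493 genes measured on that chip alone 38 rose and 72 fell. The MOE430A count fell to 2851 without undifferentiated sample 2, to 2751 without undifferentiated sample 4 and to 2501 without differentiated samples 1 and 4, and it was 12225 with 1.92% of them higher when the arrays were scaled on the hybridisation controls. The MOE430B count lay between 39 and 145 when any of the 6 samples was left out, and limma called 0 probe sets with the sample number as a block (2505 at an unadjusted p under 0.05) and 0 without differentiated samples 1 and 4 (2166 at an unadjusted p under 0.05).

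**Figure D1:**
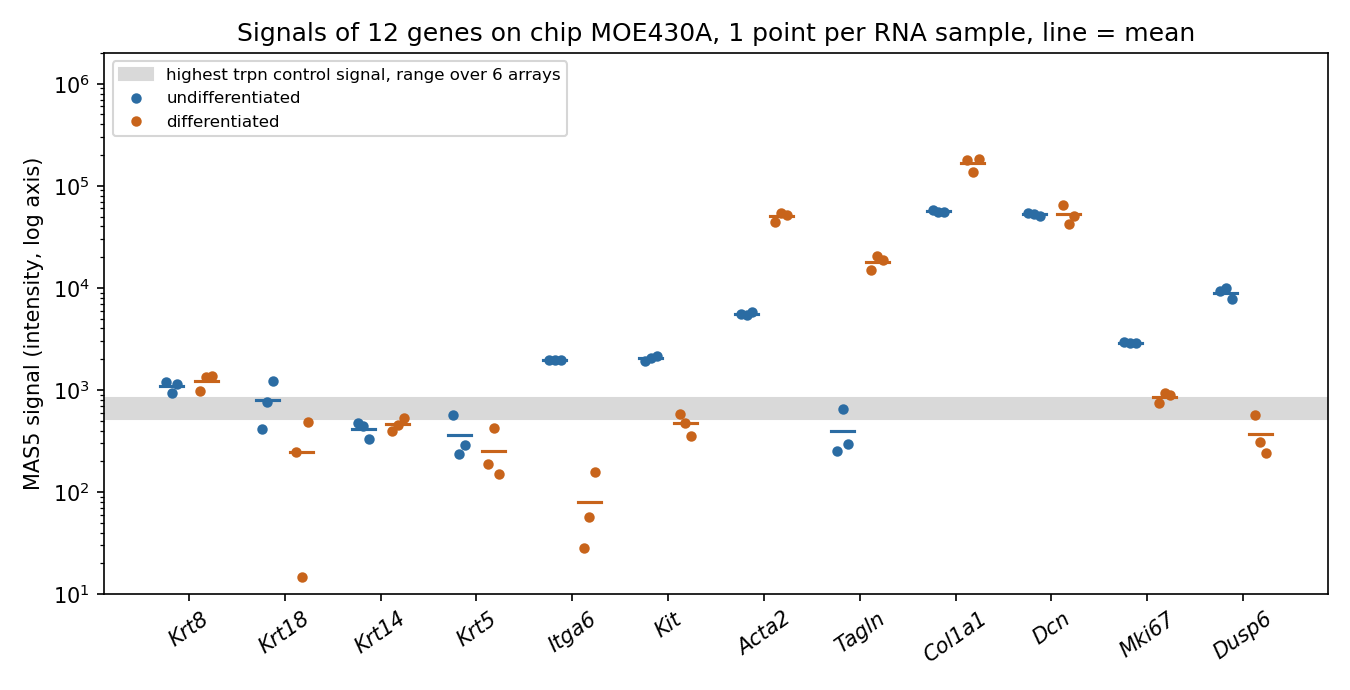
MAS5 signal on chip MOE430A (intensity, log axis) of 12 genes, with 1 point for each of the 3 undifferentiated (blue) and 3 differentiated (orange) RNA samples and a line at the mean; the grey band spans the highest trpn control signal of the 6 arrays, 515.5 to 829.8. The states are to be compared within a gene, as between 5580 and 50040 for Acta2, and not one gene with another, since probe sets differ in how they bind; Col1a1 and Dcn were added after their values were seen.

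The 10 genes named for a rise on MOE430A were ranked by fitted log2 fold change, the rule set in advance, which does not order genes with a state below the background. Thbs1, which encodes the matrix glycoprotein thrombospondin, rose by 5.76 ± 0.22 (log2, SE; adjusted p = 2.1e-05), and Mfap4, a microfibril protein, by 4.97 ± 0.18 (adjusted p = 2.1e-05). For the other 8 the undifferentiated values lay below the background. The probe set of Adm, which encodes the vasodilator peptide adrenomedullin, was at least 21.8-fold higher, that of Tagln, an actin-binding protein of smooth muscle, at least 30.9-fold, and that of Sod3, the extracellular superoxide dismutase, at least 20.5-fold. Ptx3, a secreted pentraxin of innate immunity, rose from 264.4 to 20950, the neural adhesion molecule Ncam1 from 65.1 to 7327, Reg1, a secreted lectin, from 308.3 to 16630, the granin Scg2 from 280.2 to 12570 and the matrix protein Abi3bp from 163.2 to 7517. On MOE430B the rises named by the same rule were those of the collagen gene Col8a2 (adjusted p = 0.0126), Wfdc17 (adjusted p = 0.00606) and the transcriptional regulator Mn1 (adjusted p = 0.00401).

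The same ranking, with the same limit, gave 10 falls on MOE430A. Egr2, a zinc-finger transcription factor, changed by -4.41 ± 0.23 (log2, SE; adjusted p = 4.58e-05), and Mmp10, a matrix metalloproteinase, by -4.60 ± 0.48 (adjusted p = 0.000755). In differentiated samples 1, 2 and 4 the background was 829.8, 691.2 and 670.4. Egr2 read 610.1, 696.6 and 356.3 there and Mmp10 236.4, 960.6 and 193.9, so the sizes of both changes are uncertain. Etv4, an ETS transcription factor, fell from 3935 to 108.1, and its probe set was at least 5.41-fold lower. The other genes in this group were Dusp6, Pla2g7, which encodes a secreted phospholipase (9186 to 216.6), the chemokine gene Ccl12 (4187 to 76.7), the Wnt inhibitor gene Apcdd1 (6162 to 169.5), Itih5 (6939 to 297.1), the peptide hormone gene Cck (2312 to 59.1) and Scml4 (3227 to 107.3). Their differentiated values all lay below the background. The falls of their probe sets were bounded at no more than at least 3.18-fold for Cck to at least 12.6-fold for Pla2g7. On MOE430B the falls named were those of Dusp4, another ERK-induced phosphatase, whose probe set was at least 16-fold lower (adjusted p = 0.00894), Fam167a (adjusted p = 0.00356) and Frem1, an extracellular matrix protein (adjusted p = 0.00228).

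Of 32 gene lists fixed in advance, camera called 12, 8 higher and 4 lower in the differentiated samples. The cell cycle list alone was also called with an estimated correlation between genes. The estimate lay below the preset 0.01 for glycolysis and hypoxia (-0.026), insulin-like growth factor (-0.0493) and Wnt genes (-0.00913). So it did for cholesterol (-0.00511), adipocyte (-0.0401) and unfolded protein genes (0.00814). The lost calls of those lists cannot come from a higher correlation. The other lists that lost their call had estimates from 0.031 for YAP and serum response factor to 0.208 for contractile genes. The counts of members below use the adjustment over all probe sets of a chip, and list medians are over the genes of MOE430A. Scaled on the hybridisation controls, which put the median of all tested MOE430A probe sets at -1.12, the lists called higher other than the adipocyte list had fewer rises: 4 higher and 5 lower for contractile, 4 and 6 for matrix, 6 and 7 for YAP and serum response factor, 3 and 5 for glycolysis and hypoxia, 5 and 11 for Wnt, 4 and 3 for insulin-like growth factor and 1 and 15 for unfolded protein genes. The adipocyte list had 1 higher and 1 lower. All of these but the unfolded protein list were still called higher relative to other genes. The lists called lower had more falls under that scaling and 0 rises, with 40 cell cycle, 24 growth factor response, 19 cholesterol synthesis and 33 oxidative phosphorylation genes lower. Lists that were not called had more falls under it too. Among them were interferon genes with 0 higher and 20 lower, Notch with 0 and 14, stem and progenitor with 1 and 12, proteases with 3 and 13, glutathione with 2 and 13 and cytokines with 2 and 11.

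Cell cycle and DNA replication genes were lower together. Of 40 measured genes 36 fell, 0 rose and 4 did not pass, and 38 fell when adjusted over the list alone. The fall in Mki67 was -1.68 ± 0.13 (log2, SE; adjusted p = 0.000211). Mcm6, a subunit of the replicative helicase, fell from 2469 to 122.6, at least 3.35-fold on its probe set. Bub1b, a spindle checkpoint kinase, fell from 1457 to 162.4, at least 1.99-fold. Of the 2 other probe sets tested for each, 1 also fell and 1 on MOE430B pointed up without passing. Over the list the median was -1.49 with an adjusted p = 7.79e-21 by camera, and adjusted p = 0.0302 with an estimated correlation. Leaving out differentiated samples 1 and 4, 30 of its genes fell and 0 rose.

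Growth factor and ERK response genes were also lower. By the probe set that stands for each gene, 16 of 27 measured genes fell and 2, Spry2 and Egr3, rose, and 18 fell and 2 rose when adjusted over the list alone. Dusp4, Dusp6 and Egr2 were among those that fell. Spry2, an inhibitor of receptor tyrosine kinase signalling, rose by 0.62 ± 0.15 (log2, SE; adjusted p = 0.0206). Egr3 gave opposite results on its probe sets, so no direction can be given for the gene: that of MOE430A rose by 1.72 ± 0.32 (adjusted p = 0.00858), and that of MOE430B fell from 9298 to 224.6, below the background, and was at least 3.87-fold lower (adjusted p = 0.00374). The list's median was -0.64 with an adjusted p = 6.57e-06, and adjusted p = 0.173 with an estimated correlation. With differentiated samples 1 and 4 left out, 11 fell and 1 rose.

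Fibrillar and interstitial matrix genes rose as a group. Of 26 measured genes 20 rose, 3 fell and 3 did not pass, and 21 rose and 4 fell when adjusted over the list alone. Besides Thbs1, Lox, an enzyme that cross-links collagen and elastin, rose by 4.96 ± 0.14 (log2, SE; adjusted p = 1.52e-05). The matrix glycoprotein gene Tnc changed by -1.15 ± 0.13 (adjusted p = 0.000913) and the collagen VI gene Col6a2 by -0.85 ± 0.12 (adjusted p = 0.0024). Over the list the median was 1.40 with an adjusted p = 7.51e-08, and adjusted p = 0.173 with an estimated correlation. Without differentiated samples 1 and 4, 18 rose and 2 fell. Col1a1, chosen after its values were seen, had signals of 56410 and 165500 in the undifferentiated and differentiated samples.

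Smooth muscle contractile genes were higher, among them Tagln, Myl9 and Acta2. Of 21 measured genes 11 rose, 2 fell and 8 did not pass, and 14 rose and 3 fell when adjusted over the list alone. Myl9, a myosin regulatory light chain, was at least 14.3-fold higher on its probe set, and Acta2 rose by 3.14 ± 0.13 (log2, SE; adjusted p = 2.9e-05). The smoothelin gene Smtn changed by -0.63 ± 0.12 (adjusted p = 0.00939), and Mme, a surface peptidase of myoepithelial and other cells, fell from 1336 to 292.4, at least 1.84-fold on its probe set. The list's median was 0.62 with an adjusted p = 0.000642, and adjusted p = 0.288 with an estimated correlation. Leaving out differentiated samples 1 and 4, 9 rose and 1 fell.

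Target genes of YAP and serum response factor, regulators that respond to attachment and the actin skeleton, were higher. Of 22 measured genes 12 rose and 0 fell, the same counts as when adjusted over the list alone. Ccn2, a matricellular growth factor, rose by 3.44 ± 0.28 (log2, SE; adjusted p = 0.000234) and Amotl2, an angiomotin, by 3.36 ± 0.14 (adjusted p = 2.86e-05). Over the list the median was 1.07 with an adjusted p = 3.33e-06, and adjusted p = 0.0948 with an estimated correlation. With differentiated samples 1 and 4 left out, 8 rose and 0 fell.

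Glycolysis and hypoxia-response genes were higher, and the oxidative phosphorylation list was called lower although most of its genes did not pass. Of 23 measured glycolysis and hypoxia genes 16 rose and 1 fell, and 20 rose and 1 fell when adjusted over the list alone. P4ha2, a subunit of collagen prolyl hydroxylase, rose by 2.46 ± 0.16 (log2, SE; adjusted p = 9.33e-05), and the phosphofructokinase gene Pfkp changed by -0.46 ± 0.14 (adjusted p = 0.046) on its brightest MOE430A probe set but did not pass on the others. The list's median was 0.92 with an adjusted p = 1.15e-07, and adjusted p = 0.0513 with an estimated correlation. Of 33 oxidative phosphorylation genes 7 fell and 0 rose, but only 1 fell when adjusted over the list alone and only 1 with scaling on the poly-A controls. Cycs, which encodes cytochrome c, changed by -1.06 ± 0.12 (adjusted p = 0.000878), though its MOE430B probe set pointed up without passing. Sdhd, a subunit of succinate dehydrogenase, changed by -0.78 ± 0.22 (adjusted p = 0.0387). That list's median was -0.30 with an adjusted p = 0.000642, and adjusted p = 0.197 with an estimated correlation. Without differentiated samples 1 and 4, 11 glycolysis and hypoxia genes rose and 0 fell, and 2 oxidative phosphorylation genes fell.

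**Figure D2:**
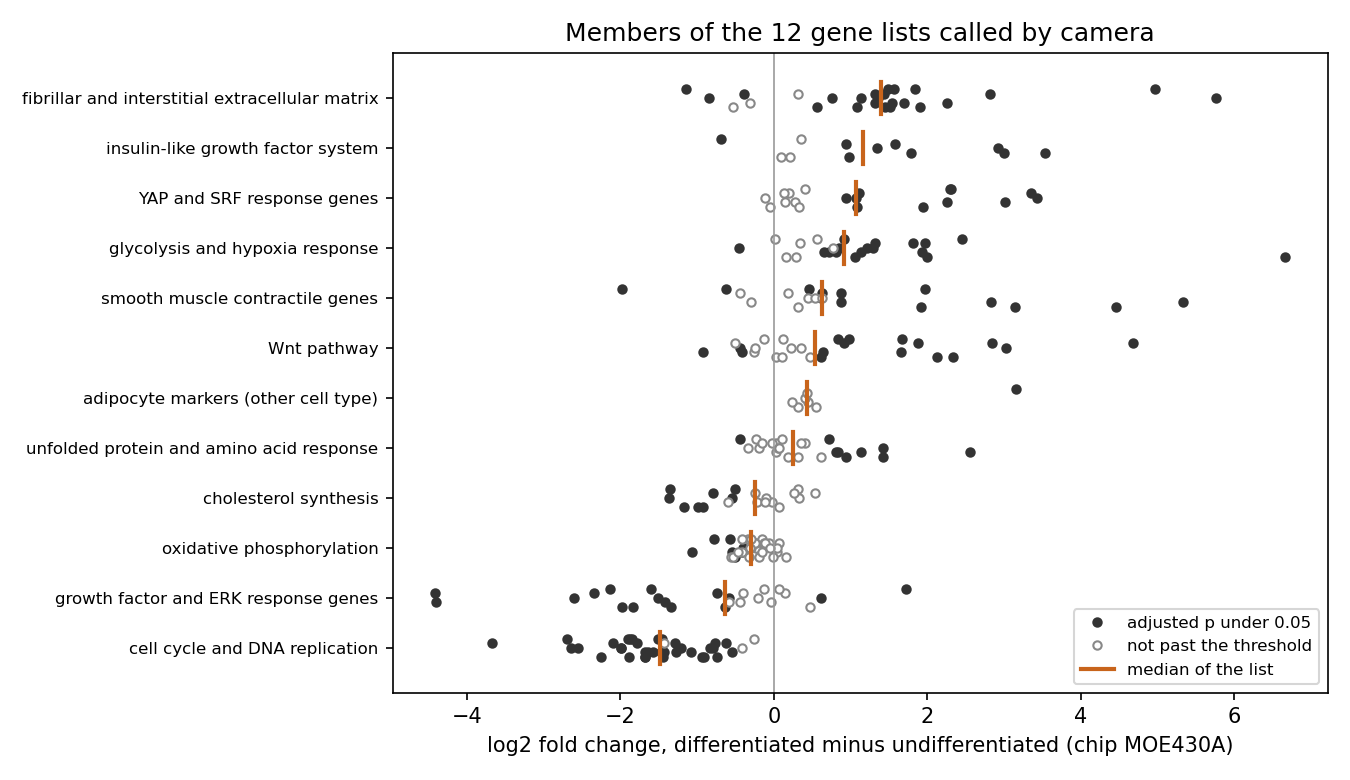
Log2 fold change (differentiated minus undifferentiated, chip MOE430A, 3 samples per state) of each member of the 12 lists called by camera; filled points passed an adjusted p of 0.05, open points did not, fitted values of genes with a state below the background are not bounds, and the orange bar is the median of the list. The medians run from -1.49 for the cell cycle to 1.40 for the matrix. Scaled on the hybridisation controls, the median of all tested probe sets lay at -1.12. These medians kept their signs relative to it, but taking off that shift largely undoes the scaling, so this does not test them.

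Genes of the Wnt pathway were higher as a list, and the 2 named for the largest rises encode secreted inhibitors. Members of other kinds read higher too, such as the receptor gene Fzd2 (2927 to 11030) and Dvl1 (1969 to 3061), while the receptor gene Fzd7 read lower (2276 to 1597). The rise of the list is thus not one of inhibitors alone. Of 31 measured genes 13 rose and 3 fell, and 14 rose and 4 fell when adjusted over the list alone. Sfrp2, a secreted Wnt antagonist, was at least 25.2-fold higher on its probe set, and its relative Sfrp1 rose by 3.03 ± 0.22 (log2, SE; adjusted p = 0.000165). Axin2, a feedback target of the canonical pathway, changed by -0.92 ± 0.18 (adjusted p = 0.01) and Ctnnb1, which encodes beta-catenin, by -0.44 ± 0.12 (adjusted p = 0.0367). Over the list the median was 0.54 with an adjusted p = 0.00153, and adjusted p = 0.109 with an estimated correlation. Leaving out differentiated samples 1 and 4, 11 rose and 1 fell.

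Of 12 measured genes of the insulin-like growth factor system 8 rose and 1 fell, the same counts as when adjusted over the list alone. The probe set of the binding protein gene Igfbp2 was at least 3.41-fold higher and that of the adaptor gene Grb14 at least 3.91-fold, while that of the growth factor gene Igf2 was at least 1.43-fold lower. The list's median was 1.16 with an adjusted p = 0.000171, and adjusted p = 0.0948 with an estimated correlation. Of 24 genes of the unfolded protein and amino acid response 8 rose and 1 fell, also when adjusted over the list alone. Trib3, a pseudokinase, rose by 2.56 ± 0.15 (log2, SE; adjusted p = 6.17e-05), the transcription factor gene Ddit3 by 1.42 ± 0.13 (adjusted p = 0.000427), and the serine hydroxymethyltransferase gene Shmt2 changed by -0.44 ± 0.12 (adjusted p = 0.0352) on its brightest probe set but did not pass on the others. That list's median was 0.25 with an adjusted p = 0.0173, and adjusted p = 0.173 with an estimated correlation; scaled on the hybridisation controls, its adjusted p was 0.0546, and over all alternatives it ranged from 2e-04 to 0.173. With differentiated samples 1 and 4 left out, 7 genes of the first list rose and 1 fell, and 8 of the other rose and 0 fell.

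Cholesterol synthesis genes were lower as a list. Of 20 cholesterol synthesis genes 8 fell and 0 rose, and 9 fell when adjusted over the list alone. Idi1 and Msmo1, enzymes of the pathway, changed by -1.36 ± 0.19 (log2, SE; adjusted p = 0.00253) and -1.35 ± 0.18 (adjusted p = 0.00228), though the MOE430B probe set of Msmo1 pointed up without passing. Over the list the median was -0.25 with an adjusted p = 0.0174, and adjusted p = 0.173 with an estimated correlation. Without differentiated samples 1 and 4, 7 of these genes fell. Of 21 fatty acid synthesis and storage genes 7 fell and 2 rose, also when adjusted over the list alone, and the list was not called over its 17 genes of MOE430A (adjusted p = 0.0599). It was called lower with its MOE430B genes added (adjusted p = 0.0359), without undifferentiated sample 2 (0.0482), with scaling on the hybridisation controls (0.0367) and by fry (0.000122); over all alternatives the adjusted p ranged to 0.197. Without differentiated samples 1 and 4, 3 fatty acid genes fell and 0 rose, and under the hybridisation scaling 15 fell and 0 rose. The desaturase gene Scd1 changed by -2.66 ± 0.14 (adjusted p = 5.32e-05) and the elongase gene Elovl6 by -1.40 ± 0.15 (adjusted p = 0.000895), while Me1, malic enzyme, rose by 0.78 ± 0.12 (adjusted p = 0.00455) and Gpam, which starts glycerolipid synthesis, by 0.43 ± 0.13 (adjusted p = 0.0474).

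Neither list of mammary epithelial markers was called. Of 14 measured luminal markers 1 rose, 1 fell and 12 did not pass. Of 17 basal markers 4 rose, 1 fell and 12 did not pass. Adjusted over the list alone, the counts were the same in both. Scaled on the hybridisation controls, 0 luminal markers were higher and 7 lower, and 1 basal marker was higher and 10 lower. Camera gave an adjusted p = 0.833 for luminal and 0.7 for basal markers; fry called the basal list higher (adjusted p = 0.0366), and over all alternatives the basal adjusted p ranged to 0.902. The luminal median was 0.18 over all measured genes and -0.01 over those of MOE430A, where the mean was -0.28 and the test pointed down. The receptor gene Kit, a marker of luminal progenitors, fell from 2037 to 470.4, at least 2.8-fold on its probe set, and Itga6, the alpha-6 integrin of basal and progenitor cells, from 1963 to 80.5, at least 2.7-fold. Dst, a cytoskeletal linker of hemidesmosomes, rose by 1.94 ± 0.21 (log2, SE; adjusted p = 0.000838), a probe set of the epithelial transcription factor gene Grhl2 by 0.87 ± 0.22 (adjusted p = 0.026) while the other one tested pointed down without passing, and the probe set of Cdh3, P-cadherin, was at least 1.67-fold higher. Leaving out differentiated samples 1 and 4, 0 luminal markers rose and 3 fell, and 3 basal markers rose and 1 fell.

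Among the keratin genes Krt8 had 1091 ± 144.6 and 1229 ± 228.3 (adjusted p = 0.549) in the undifferentiated and differentiated samples, and Krt18 803.7 ± 411.6 and 248.3 ± 234.6 (adjusted p = 0.102). The probe sets of Krt14 (417.9 and 460.4, adjusted p = 0.612), Krt5 (363.7 and 252.0, adjusted p = 0.407), Trp63 (520.1 and 563.3, adjusted p = 0.829) and Esr1 (361.1 and 878.6, adjusted p = 0.223) lay below the background of their chip in both states. Krt19 and Cd24a were too dim to be tested, and no probe set carried the symbol Ly6a. Of the 50 luminal and basal markers on the chips, 10 had a probe set above the trpn controls on all 6 samples and 25 had none above them on any. Over all named genes these shares were 39.8% and 36.2%. The 10 markers were Tspan8, Krt8, Elf3, Grhl2, Pdpn, Egfr, Cd44, Cav1, Igfbp5 and Snai2. Epcam lay below the background on its MOE430A probe set, but its MOE430B probe set gave 6051 ± 3614 and 7270 ± 3104 (adjusted p = 0.808).

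Markers of fibroblasts, taken as a possible other cell type, were above the trpn controls on all 6 samples for 16 of 20 genes, against 39.8% of all named genes. Of 19 measured ones 9 rose, 2 fell and 8 did not pass, with 9 higher and 3 lower when adjusted over the list alone, and the list was not called (adjusted p = 0.102). It was called higher with scaling on the poly-A controls (adjusted p = 0.00968) or the hybridisation controls (0.000724), with the mean of all probe sets of a gene (0.0362) and by fry (0.000382); over all alternatives the adjusted p ranged to 0.288. Under the hybridisation scaling that call is relative to other genes only, since 3 markers were higher and 9 lower. Besides Mfap4, the probe set of the proteoglycan gene Ogn was at least 14.9-fold higher, while the proteoglycan gene Lum changed by -1.52 ± 0.14 (log2, SE; adjusted p = 0.00039) and Fap, a fibroblast surface protease, by -1.39 ± 0.23 (adjusted p = 0.00571). Dcn, decorin, chosen after its values were seen, had signals of 52780 ± 1884 and 52500 ± 11540 (adjusted p = 0.912). With differentiated samples 1 and 4 left out, 6 fibroblast markers rose and 3 fell.

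Milk and secretory genes gave no common direction under the reported scaling. Of 16 measured genes 2 rose, 4 fell and 10 did not pass, also when adjusted over the list alone (camera adjusted p = 0.994). The median was 0.11 against a mean of -0.17, and the test pointed down. Scaled on the hybridisation controls 0 of these genes were higher and 12 lower, and on the poly-A controls 0 and 2. Csn2, beta-casein, had 598.9 and 588.2 (adjusted p = 0.919), while Csn3, kappa-casein, changed by -1.81 ± 0.40 (log2, SE; adjusted p = 0.0156) and Plin2, a lipid droplet protein, by -1.34 ± 0.17 (adjusted p = 0.00195). B4galt1, a galactosyltransferase of lactose synthesis, rose by 0.64 ± 0.11 (adjusted p = 0.00634), and the lipase gene Cel by 0.54 ± 0.15 (adjusted p = 0.032). Of 18 squamous differentiation genes 0 passed limma's test, adjusted over the list alone or not, and 2 had an unadjusted p under 0.05 (camera adjusted p = 0.994). With scaling on the hybridisation controls 0 squamous genes were higher and 10 lower.

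Of 21 stem and progenitor associated genes 4 rose, 8 fell and 9 did not pass, with 5 higher and 8 lower when adjusted over the list alone, and the list was not called, with a median of -0.33 (adjusted p = 0.102). It was called lower with a median of -0.87 under the filters at 50% of the trimmed mean (adjusted p = 0.00691) and at the trpn controls (0.00759), with scaling on the poly-A controls (0.0126) or the hybridisation controls (0.00825) and by fry (2.98e-05); over all alternatives the adjusted p ranged to 0.261. Besides Etv4, the surface sialomucin gene Cd34 changed by -2.86 ± 0.15 (log2, SE; adjusted p = 5.4e-05). On its probe set Aldh1a1, a retinaldehyde dehydrogenase, was at least 1.52-fold higher, and the probe set of the transcription factor gene Klf4 was at least 1.48-fold higher. Of 20 Notch pathway genes 1 rose, 2 fell and 17 did not pass, with 0 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.994). The receptor gene Notch1 changed by -1.57 ± 0.13 (adjusted p = 0.000297) and a probe set of Notch2 by -0.61 ± 0.17 (adjusted p = 0.0354), while the other one tested for Notch2 pointed up without passing; the ligand gene Dll4 passed (adjusted p = 0.0422) with both states below the background. The Notch median was 0.14, the mean -0.01 and the test pointed down.

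Of 12 Hedgehog pathway genes 1 rose and 1 fell, with 2 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.836). Gas1, a Hedgehog co-receptor, rose by 0.60 ± 0.11 (log2, SE; adjusted p = 0.00895), and the probe set of the transcription factor gene Gli2 was at least 1.54-fold lower. Of 23 TGF-beta and BMP pathway genes 7 rose and 7 fell, with 8 higher and 9 lower when adjusted over the list alone (camera adjusted p = 0.994). Scaled on the hybridisation controls, 1 of them was higher and 15 lower. Ltbp2, a latent TGF-beta binding protein, rose by 2.65 ± 0.16 (adjusted p = 7.97e-05) and the co-receptor gene Tgfbr3 by 1.70 ± 0.12 (adjusted p = 0.000141), and the probe set of Id2, an inhibitor of helix-loop-helix factors, was at least 3.57-fold lower and that of Bmp2 at least 1.28-fold. The medians, 0.17 for Hedgehog and 0.12 for TGF-beta and BMP, differed in sign from the means, -0.04 and -0.12, and the tests pointed up and down.

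Basement membrane and protease genes moved both ways. Of 14 basement membrane genes 2 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.894), with a median of 0.11, a mean of -0.02 and a test that pointed down. The collagen IV gene Col4a5 rose by 1.97 ± 0.18 (log2, SE; adjusted p = 0.000402) and the perlecan gene Hspg2 by 0.80 ± 0.18 (adjusted p = 0.0163), while Col18a1 changed by -2.16 ± 0.18 (adjusted p = 0.000256) and Col4a1 by -0.87 ± 0.14 (adjusted p = 0.00447). Of 20 matrix proteases and inhibitors 6 rose and 7 fell, also when adjusted over the list alone (camera adjusted p = 0.872), with a median of 0.13, a mean of -0.06 and a test that pointed down. The aggrecanase gene Adamts5 rose by 3.39 ± 0.19 (adjusted p = 5.58e-05) and Adamts1 by 2.37 ± 0.12 (adjusted p = 4.13e-05), and besides Mmp10 the gelatinase gene Mmp9 changed by -2.00 ± 0.19 (adjusted p = 0.000501).

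Of 20 p53 and cell cycle inhibitor genes 6 rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.994). Their median was -0.15 and their mean 0.16, and the test pointed up. Scaled on the hybridisation controls, 1 of them was higher and 13 lower. Igfbp3 and Igfbp7, which encode secreted binding proteins, rose by 3.09 ± 0.30 (log2, SE; adjusted p = 0.000572) and 1.92 ± 0.15 (adjusted p = 0.000198), the p53 ligase gene Mdm2 changed by -1.20 ± 0.28 (adjusted p = 0.0208), and the probe set of Pmaip1, a death-promoting BCL2 relative, was at least 1.22-fold lower. Of 21 glutathione and oxidant defence genes 7 rose and 7 fell, with 9 higher and 9 lower when adjusted over the list alone (camera adjusted p = 0.872). Besides Sod3, Gpx3, a secreted glutathione peroxidase, rose by 2.96 ± 0.15 (adjusted p = 4.28e-05), while the probe set of the glutathione transferase gene Gsta4 was at least 3.91-fold lower and that of the quinone reductase gene Nqo1 at least 1.72-fold. That list had a median of -0.01 and a mean of 0.01, and camera pointed down, while fry called the list higher (adjusted p = 0.0165, over all alternatives up to 0.947).

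Of 23 cytokine, chemokine and NF-kB target genes 7 rose and 5 fell, with 9 higher and 6 lower when adjusted over the list alone (camera adjusted p = 0.67). The probe set of the acute-phase gene Saa3 was at least 9.94-fold higher and that of the chemokine gene Cxcl5 at least 1.78-fold, while the chemokine gene Ccl2 changed by -2.78 ± 0.17 (log2, SE; adjusted p = 7.78e-05) and the probe set of Ptgs2, an inducible cyclooxygenase, was at least 2.43-fold lower. Of 21 interferon response genes 1 rose, 1 fell and 19 did not pass, with 0 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.488). Stat2, a signal transducer of the interferon receptor, rose by 0.42 ± 0.12 (adjusted p = 0.0407), and the probe set of Oasl2 was at least 2.02-fold lower. Of 14 antigen presentation genes 1 rose and 3 fell, with 1 higher and 4 lower when adjusted over the list alone (camera adjusted p = 0.619). The immunoproteasome gene Psmb8 changed by -1.27 ± 0.15 (adjusted p = 0.00142) and the proteasome activator gene Psme1 by -0.88 ± 0.16 (adjusted p = 0.00882), while H2-M3, a non-classical class I gene, rose by 0.61 ± 0.12 (adjusted p = 0.0101).

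Markers of 4 further cell types were counted. Of 7 measured adipocyte markers 1 rose, also when adjusted over the list alone: Lpl, lipoprotein lipase, which other cells express too, rose by 3.16 ± 0.15 (log2, SE; adjusted p = 3.58e-05). That list was called with a median of 0.43 (adjusted p = 0.0429), but with adjusted p = 0.197 with an estimated correlation, 0.0635 without undifferentiated sample 4, 0.0598 without differentiated sample 4 and 0.0565 without differentiated samples 1 and 4; over all alternatives it ranged from 0.000458 to 0.197. Of 15 leukocyte markers 5 rose and 0 fell, with 5 higher and 1 lower when adjusted over the list alone, and the list was not called (camera adjusted p = 0.0599). It was called higher with the sample number (adjusted p = 0.016) or the scan session (0.0453) as a block, without undifferentiated sample 1 (0.0485), differentiated sample 4 (0.0261) or differentiated samples 1 and 4 (0.0453), with scaling on the poly-A (0.0191) or hybridisation controls (0.00825), with MOE430B genes added (0.0331) and by fry (0.0228); over all alternatives the adjusted p ranged to 0.443. Under the hybridisation scaling 0 leukocyte markers were higher and 4 lower, so that call is relative to other genes only. The probe set of the protease gene Ctss was at least 1.36-fold higher, and the complement gene C1qb passed (adjusted p = 0.046) with both states below the background. Of 15 endothelial markers 2 rose and 5 fell, with 3 higher and 5 lower when adjusted over the list alone (camera adjusted p = 0.67). The co-receptor gene Eng rose by 0.65 ± 0.16 (adjusted p = 0.0227) and the receptor gene Kdr by 0.56 ± 0.14 (adjusted p = 0.0255), the probe set of Plvap was at least 1.26-fold lower, and Pecam1 had signals of 742.7 and 253.6 (adjusted p = 0.0273).

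Of 10 Schwann cell and neural markers 2 rose and 4 fell, with 3 higher and 4 lower when adjusted over the list alone (camera adjusted p = 0.488). The list was called lower with scaling on the hybridisation controls (adjusted p = 0.0491) and by fry (0.00407); over all alternatives the adjusted p ranged to 0.639. The probe set of the neurofilament gene Nefl was at least 1.74-fold lower and that of the growth cone gene Gap43 at least 1.23-fold, and Mbp (adjusted p = 0.037) and Tubb3 (adjusted p = 0.013) passed with both states below the background.

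**Figure D3:**
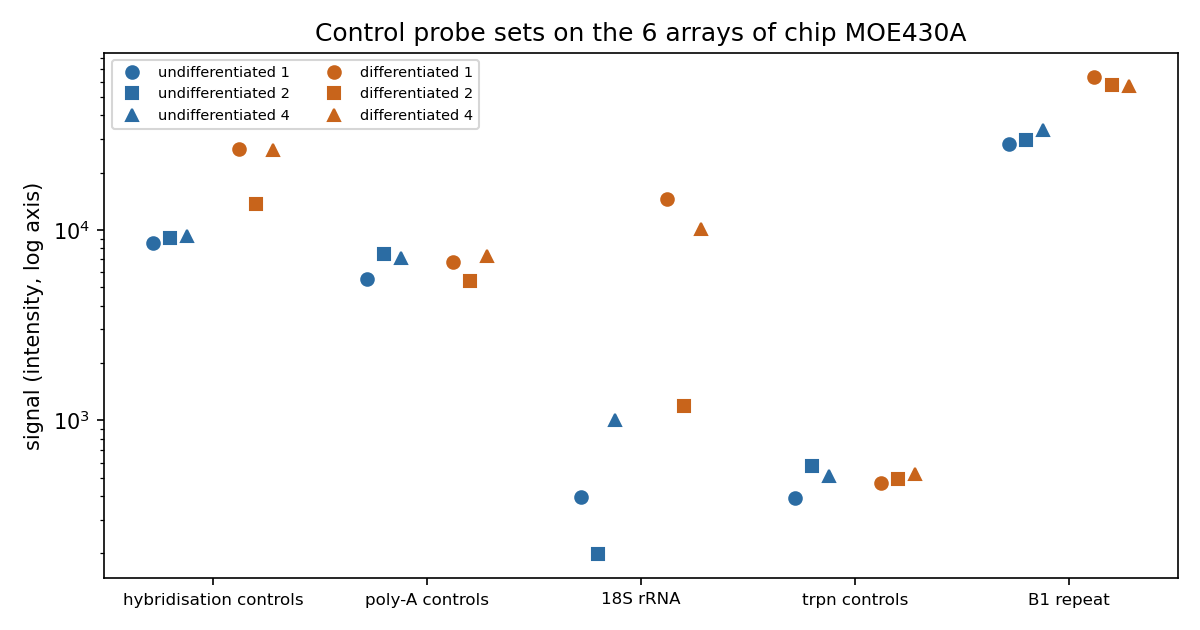
Signal (intensity, log axis) of 5 kinds of control probe set on the 6 arrays of chip MOE430A, as geometric means within a kind, with a symbol for each RNA sample (circle 1, square 2, triangle 4; blue undifferentiated, orange differentiated). The hybridisation controls read 8556 to 9300 in the undifferentiated and 13720 to 26500 in the differentiated samples, and the poly-A controls 5552 to 7447 and 5367 to 7323.

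The 3-prime over 5-prime signal ratios of the Gapdh and Actb control probe sets on MOE430A were 0.848 ± 0.025 and 1.12 ± 0.15 (SD, n = 3) in the undifferentiated and 0.886 ± 0.129 and 1.08 ± 0.052 (SD, n = 3) in the differentiated samples. Two-sided exact permutation tests gave p = 0.7 for Gapdh and 0.9 for Actb, where 0.1 is the smallest p that 3 against 3 can give. On MOE430B the ratios were 0.853 ± 0.006 and 0.792 ± 0.033 for Gapdh (exact permutation p = 0.1) and 1.096 ± 0.045 and 1.15 ± 0.045 for Actb (exact permutation p = 0.3), in the undifferentiated and the differentiated samples. A set of 100 probe sets is carried by both chips, and across them the log2 fold changes of the chips correlated at Pearson's r = 0.82, with the same sign in 81. On MOE430A 24 of them passed and on MOE430B 0, where limma tested each chip apart.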

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

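The tests on epithelial and fibroblast markers, on the scaling factor, on degraded RNA and on the control and repeat probe sets were chosen only after the result was seen.

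Control and repeat probe sets, which the comparison of genes does not use, differed between the states. On MOE430A the hybridisation controls were 2.36-fold higher in the differentiated samples and the 18S ribosomal RNA probe sets 13.04-fold (geometric means, exact permutation p = 0.1 for each, the smallest possible with 3 against 3). On MOE430B the ratios were 2.01 and 8.46, but the states overlapped in both (exact permutation p = 0.2 for each). The B1 repeat probe set, for a short interspersed repeat of the mouse genome, was 1.955-fold higher on MOE430A and 1.563-fold higher on MOE430B (exact permutation p = 0.1 for each).

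The hybridisation controls and 18S signal were highest in differentiated samples 1 and 4, with 18S signals of 14510 and 10160 against 1184 in differentiated sample 2 and 198.3 to 1004 in the undifferentiated samples. Degraded RNA was argued against by the 3-prime over 5-prime ratios of Gapdh and Actb, whose mean log2 difference between states over both chips was -0.00772, with values from -0.108 to 0.0638. The idea that these 2 samples alone carry the difference between states was argued against by a held-out pair: of 1798 MOE430A probe sets called from differentiated samples 1 and 4 against undifferentiated samples 1 and 2, 97.7% had the same sign in differentiated sample 2 minus undifferentiated sample 4. Less labelled sample RNA, made up by a larger scaling factor, is a candidate explanation for the hybridisation controls. The 9 of them shared nearly 1 factor within each differentiated array, with an SD of their log2 ratios of at most 0.246. On MOE430B, though, differentiated sample 2 had a ratio of 1.2 against 1.22 in undifferentiated sample 4. The 18S signal rose more, 13.04-fold against 2.36-fold on MOE430A, which a common scaling factor leaves unexplained. A larger volume of control mix would give the same rise of the hybridisation controls and the fluidics station differs with the state, so these stay open. The poly-A controls had a ratio of 0.969 on MOE430A and 0.902 on MOE430B, so they did not share the rise of the hybridisation controls.

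A smaller share of epithelial than of fibroblast markers stood above the background. Of 50 luminal and basal markers 10 were above the trpn controls on all 6 samples and 25 on none, against 16 and 1 of 20 fibroblast markers. Over all named genes 39.8% were above on all 6 and 36.2% on none. The epithelial share above on all 6, 20%, was near those of leukocyte (19%), endothelial (22.2%) and adipocyte markers (23.1%). Probe sets that fail whatever cell type their gene marks stay open. A two-sided Fisher's exact test of the epithelial and fibroblast counts gave p = 4.72e-06 (1.18e-05 with 1 probe set per gene). Without a reference RNA from epithelium it cannot tell poor probe sets from low expression. Cells of mesenchymal type may be the main source of the RNA, with 96.2% of 26 matrix genes above the controls on all 6 samples. That share does not tell cell types apart, since oxidative phosphorylation (100%), cholesterol synthesis (95%) and unfolded protein genes (92%) had like shares. Being above background also gives no share of the RNA, and myoepithelial cells also express several of these matrix genes. Epithelial cells that took on mesenchymal expression stay open, since no lineage mark was measured. The 10 epithelial markers above the controls do not settle it, as whether other cell types gave their signal was not tested. Krt8 was among the 10, while Cdh1, Krt5, Krt14, Krt7 and Krt19 were above the controls on 0 of 6 samples. The labels name no fibroblasts, give marker analysis as the method of purity, and report mammary development after transplantation, which argues for epithelial cells in the mammospheres.

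Fewer probe sets were called on MOE430B, 328 against 4550, although the same 6 RNA samples were hybridised. Noisier measurement on MOE430B is a likely part of it: on the 100 probe sets carried by both chips the median residual SD was 0.206 against 0.136, a ratio of 1.52 (95% bootstrap interval 1.33 to 1.81). The bootstrap here and below resampled probe sets and not arrays, so its intervals leave out the spread between hybridisations. More dim probe sets on MOE430B are a likely part of it too. Over all tested probe sets 28.6% passed on MOE430A and 1.83% on MOE430B. Among probe sets over the trpn controls, each chip adjusted within them, 42.1% and 24.8% were called, a much narrower gap. That ratio of 1.7 lies between the bounds set beforehand, so whether dim probe sets explain the whole gap stays open. Smaller differences between states among the transcripts of MOE430B were not seen in the spread of log2 fold changes net of error. The ratio was 1 (95% bootstrap interval 0.925 to 1.08). That interval lies wholly above the ratios set beforehand for this explanation, which argues against it among probe sets over the trpn controls. It reaches both sides of the bound of 1 set for its absence, so a slight difference stays open.

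Splitting the 6 samples into 3 and 3 can be done in 10 ways, too few for a share under 0.05. The real split gave 4550 probe sets on MOE430A, 328 on MOE430B and 12 lists, and 1 split in 10, the real one, reached each of these. The highest of the other splits gave 0, 0 and 9, with limma at an unadjusted p under 0.05 calling at most 395 probe sets on MOE430A and 911 on MOE430B in them. Each of the other splits mixes the states, so the difference between states adds to the spread within its groups. Few probe sets can then pass by construction, and the counts of 0 do not show what chance alone gives.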

How the results depend on the processing

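Scaling on the control probe sets, the filter at the trpn controls and leaving out differentiated samples 1 and 4 were tests chosen only after the result was seen. Against 4550 on MOE430A and 328 on MOE430B, leaving out 1 sample at a time gave 2751 to 3870 and 39 to 145 probe sets, a loss that fewer samples bring by construction. Leaving out differentiated samples 1 and 4 gave 2501 and 0 (limma; 2166 at an unadjusted p under 0.05), with the lone differentiated sample assumed to vary like the undifferentiated ones. With the sample number as a replicate block limma gave 3563, of which 3389 were shared with the 4550, and 0 (2505 at an unadjusted p under 0.05); correlations of like-numbered samples were 0.039, -0.019 and 0.020 on MOE430A, so the samples were not treated as paired. The scan session block gave 3158 and 58, in effect the comparison within session 1.

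Scaling on the poly-A controls gave 2534 and 172, and on the hybridisation controls 12225 with 1.92% higher and 1411 with 2.41% higher; the latter moved the median of all log2 fold changes to -1.12 and -0.90, which its construction explains. The filter at the trpn controls gave 829 on MOE430B, adjustment over both chips 792, and a trend and robust prior 838; a log2 fold change of at least 1 gave 1654 on MOE430A. For the last 4 and the poly-A scaling the cause was not tested, beyond fewer tests under the filter. Of 32 lists 12 were called, 1 with an estimated correlation and 19 with fry, which tests a list on its own. Glutathione genes turned from down in camera to up in fry (median -0.0149, adjusted p = 0.0165, range over the alternatives 0.0165 to 0.947); the cause was not tested. The other settings called 11 to 16 lists, and 10 lists were called in all 22 settings, the reported one included, other than the estimated correlation and fry. The unfolded protein list lost its call when scaled on the hybridisation controls. The adipocyte list lost it with no filter (adjusted p = 0.132), without undifferentiated sample 4, differentiated sample 4 or differentiated samples 1 and 4, and with the mean of all probe sets (0.0591), in a range of 0.000458 to 0.197, and had too few genes under the 2 stricter filters.

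No named gene changed sign in any setting, taken relative to the median shift where scaling moved it. Taking off that shift largely undoes the scaling, so the hybridisation scaling does not test the signs. Before the shift is taken off, small rises can turn to falls under it. Of 118 that passed, 95 to 107 still passed when a sample was left out, 100 with the replicate block and 88 of 113 with a value without differentiated samples 1 and 4. Signal over background limits folds: 602 of 2771 genes that passed have 1 state below the background and a further 139 have both.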

Other observations

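The groups here, and their tests, were chosen only after the result was seen, so the counts are descriptions. Of 12 measured genes of retinoid handling 4 rose, 4 fell and 4 did not pass. The cellular retinoic acid binding protein gene Crabp1 fell from 57440 ± 1063 to 4929 ± 518.6 (SD, n = 3), a log2 change of -3.53 ± 0.13 (SE; limma adjusted p = 2.1e-05), and the probe set of Crabp2 was at least 2.26-fold lower (adjusted p = 5.22e-05). Stra6, a receptor for retinol uptake, was at least 1.72-fold lower on its probe set (adjusted p = 0.000133), while the retinaldehyde reductase gene Dhrs3 rose by 0.97 ± 0.16 (log2, SE; adjusted p = 0.00481). Of 10 measured non-coding RNA genes, mostly hosts of small nucleolar RNAs, 9 rose, 0 fell and 1 did not pass. On its brightest MOE430A probe set Malat1, a nuclear RNA, rose by 4.25 ± 0.13 (log2, SE; adjusted p = 1.61e-05) and Gas5, a growth-arrest host gene, by 2.52 ± 0.12 (adjusted p = 3.93e-05); some of their other probe sets did not pass.

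Of 9 measured mast cell genes 5 fell, 0 rose and 4 did not pass. The brighter probe set of the tryptase gene Tpsb2 was at least 2.37-fold lower (adjusted p = 5.84e-05) where its dimmer one did not pass, Tpsab1 fell from 3303 to 638.7 (adjusted p = 0.00036), and the carboxypeptidase gene Cpa3 from 1450 to 537.0 (adjusted p = 0.00495). The 5 measured complement genes passed as higher, but C1qb lay below the background in both states. Serping1, the C1 inhibitor, rose by 2.08 ± 0.16 (log2, SE; adjusted p = 0.000203) and C1s1, a protease of the classical pathway, by 1.16 ± 0.17 (adjusted p = 0.00303).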
